A study of Mus musculus with 96 samples.

How the data were processed

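Single-cell RNA-seq values were analysed for 96 cells of murine marrow, labelled as erythroid precursors of genotype Rpl11 +/lox. Per the labels' protocols, cells were isolated on the Fluidigm C1 system, cDNA was made and amplified with SMART-Seq chemistry, and libraries were prepared with the Nextera XT kit. Per the submitters' processing notes, TopHat2 version 2.0.9 and the genome build mm9 were used, and other steps are not given in the sources used here. The deposited values are RPKM (reads per kilobase of transcript per 1000000 mapped reads) made by the authors, with 34899 transcript entries for 24321 gene symbols, of which 5556 had more than 1 transcript. Column sums ran from 202287 to 2810247 with a median of 1443581, and the values were used as deposited, without a count model. A gene was given, in each cell, the value of its highest transcript, a choice made after the data were seen, since the design did not state one. Exact zeros were read as listed at 0. The reference annotation at hand was of another genome build than mm9, so no coordinates are given and it served only for transcript lengths.

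Depth is not stated by RPKM, so it was estimated per cell from the steps between low values, which are multiples of the value of 1 read at a given transcript length. Lengths were found for 97.6% of transcripts, values within 0.06 of a whole number counted as whole, and the estimate recovered simulated depths at a ratio of 1.01. Whether a unit was a read or a pair was not settled, so absolute depths could be off by a factor of 2. All 58 kept cells had an estimate, as did 23 of 27 cells under the gene minimum.

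All 96 cells have the same group label and no animal is named, so the cells count as 1 sample and no p-value, standard error or correlation over cells was computed. Shares have exact Clopper-Pearson intervals at 95%, and these and floors of 3 reads cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Values were analysed as log2(RPKM + 1), which understates differences of genes with low values. Cells were kept with at least 1000 genes at 1 RPKM or more. A cell was set aside when at least 3 markers, and at least 50% of the measured markers, of a non-erythroid list were at 10 RPKM or more. These lists were megakaryocyte, mast cell or basophil, neutrophil, monocyte or macrophage, B cell, T or NK cell, stem or multipotent cell, and stroma or endothelium, and together with early progenitor, late progenitor and erythroblast lists they make 11 marker lists. No doublet caller was run on so few cells, and captures of 2 cells were weighed through markers instead.

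Clusters were built from genes at 1 RPKM or more in at least 10 kept cells, after leaving out all genes of the marker lists and of 18 gene lists. The remaining genes, in alphabetical order, were split alternately into 2118 genes for clustering and 2118 held-out genes. The 1000 most variable genes of the clustering set were centred and reduced to 10 principal components, and Ward linkage gave 3 clusters as the number from 3 to 6 with the largest mean silhouette. Clusters were ordered by the mean log2 value of erythroblast markers, and the lowest and highest among clusters of at least 5 cells were the ends compared. A gene was called higher or lower when its mean log2 values differed by at least 1, in the same direction in each run code with at least 3 cells in both ends. Run codes were those of the sample descriptions, whereas the titles give 1 code to all cells. For a list, the median difference over its members was set against 10000 random lists of the same size, as a percentile. These were matched on mean expression over the cells of the 2 clusters compared. The gene lists were cytoplasmic ribosomal proteins, ribosome biogenesis, heme synthesis, heme export and breakdown, iron handling, globin and globin chaperone, erythroid transcription factors, p53 targets, S phase, G2 and M phase, cyclin-dependent kinase inhibitors and G1 cyclins, survival and apoptosis, EPO and STAT5 responsive genes, integrated stress response, immediate early and heat shock, oxidative stress defence, interferon response, and sex-linked genes. Of the listed symbols, 2 of the heme export list and 1 of the globin list were not analysed here.

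Genes named in the text were Rpl11, the 4 members of each list with the largest differences among those detected in at least 50% of the cells of an end cluster, and the 10 held-out genes with the largest difference in each direction, with the same direction within run codes. The 10 genes that set each cluster apart from all other kept cells define it and are no result of a comparison. A gene that the rule names in the ribosomal protein list is not reported here. Some members of the globin, heme, p53 and factor lists were named as well where a sentence needed their value, and in other lists further members that passed the size rule were named after their values were seen. The groups, markers, lists, rules and the alternatives other than those said to be added later were fixed before the data were examined. Genes named in cells outside the clusters, and Plac8, were chosen after their values were seen.

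The clustering and the size rule were tested on simulated data of 4236 genes for the comparison of clusters 3 and 1. Of 100 genes changed by 2 on the log2 scale 73 were called, of 100 changed by 4 all 100 were called, and 304 of 4036 unchanged genes (7.53%) were called as well. All 60 simulated cells were placed in their planted group, and 39 of 40 random lists fell in the central 95% of percentiles. These values were drawn gene by gene from cluster 3 cells, without the co-expression of real lists or differences between cells in genes detected. The check thus does not show that the percentiles or the size rule are calibrated for the real data. Alternatives were pseudocounts of 0.1 and 10, rescaling to a total of 1000000 or by each cell's median, other minimums of genes per cell, no cell set aside, no filter on low genes, clustering on the held-out genes, 2 to 6 clusters, k-means, 5 or 20 components, 500 or 2000 variable genes, leaving out each run code, and other detection limits, and, added later, the size rule without run codes and a minimum of 2000 genes with clusters held. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.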

Results

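RNA was sequenced from 96 single cells of mouse bone marrow, all labelled as erythroid precursors of C57BL/6 mice heterozygous at Rpl11, which encodes a protein of the large ribosomal subunit. The series describes cells from the burst-forming unit-erythroid (BFU-E), an early red cell progenitor, to the basophilic erythroblast, a nucleated red cell precursor. Cells were captured on a Fluidigm C1 system, where Ter119, a surface protein of erythroblasts, was imaged, and no image values were used here. All cells carried 1 group label, and no wild-type cells and no separate animals were named, so the comparisons are between groups of cells found in the data, with n = 1 group and no test. SDs are over cells and intervals are exact Clopper-Pearson intervals at 95%, which cover counting error only. At least 1000 genes at 1 RPKM or more were listed in 69 cells, and the other 27 (28.1%, 19.4% to 38.2%) were left out of the comparisons. In units of 1000 reads, estimated depth in the 58 cells kept was 7370 at the median (1540 to 23269), with a median of 1955.5 genes per cell (1003 to 5507).

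Rpl11 was listed at 1 RPKM or more in 41 of the 58 kept cells (70.7%, 57.3% to 81.9%). Its median log2 value was 6.36, with quartiles of 0.15 and 8.24 and an SD of 3.65 over cells. By median RPKM it ranked 67 of 79 cytoplasmic ribosomal protein genes, and its median rank within a cell was 58 (SD 14.9). Rpl11 differed widely between the clusters described next, with a median of 323 RPKM in cluster 1, 483 RPKM in cluster 2 and 1.60 RPKM in cluster 3. It was detected in 12 of 12, 11 of 11 and 18 of 35 cells of these clusters (51.4%, 34.0% to 68.6%, in cluster 3). Without wild-type cells, whether Rpl11 was at a lower dose than normal was not assessed.

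Of the 69 cells with enough genes, 11 (15.9%, 8.24% to 26.7%) carried transcripts of other blood lineages and were set aside. The neutrophil list, made of genes for granule proteins and related products, was met by 7 cells, in which Mpo (myeloperoxidase) had a median of 11446 RPKM. The monocyte or macrophage list was met by 5 cells, 3 of which also met the neutrophil list. Another cell listed the basophil genes Prss34 at 45416 RPKM and Mcpt8 at 19707 RPKM, and a further cell listed the T or NK cell genes Nkg7 at 8032 RPKM and Gzma at 3780 RPKM. The B cell, megakaryocyte, stem or multipotent cell and stroma or endothelium lists were met by 0 cells. The 11 cells listed Hba-a1, an alpha-globin gene, at a median of 252 RPKM, against 374460 RPKM in the kept cells. Among the kept cells, 4 had fewer than 3 late progenitor and fewer than 3 erythroblast markers at 10 RPKM, and listed Plac8 at 3843 to 4499 RPKM. They also listed myeloid genes, with 4 monocyte markers and Ly6c2 at 10578 RPKM in cell 33, 3 monocyte markers and Irf8 at 815 RPKM in cell 60, 4 neutrophil and 3 monocyte markers and Mpo at 371 RPKM in cell 3, and 2 neutrophil and 2 monocyte markers in cell 68. Of 10 early progenitor markers, cells 3, 33, 60 and 68 had 5, 2, 2 and 6 at 10 RPKM. Set-aside cell 77 also had 6, so these markers did not tell early progenitors from myeloid cells. Of these 4 cells, 3 fell in cluster 1 and 1 in cluster 2. These 4 are called marker-poor cells, and many differences from cluster 1 moved when they were left out.

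The 58 kept cells formed 3 clusters along a gradient of alpha-globin. Cluster 3 scored highest on erythroblast markers and held 35 cells (60.3%, 46.6% to 73.0%). It listed Hba-a1 at a median of 443162 RPKM, and 13 of 17 erythroblast markers were detected in at least 50% of its cells, a count that was 14 in cluster 2 and 13 in cluster 1 and so did not set cluster 3 apart. Cluster 2 held 11 cells (19.0%). All 10 markers of the late progenitor, the colony-forming unit-erythroid (CFU-E), were detected in at least 50% of its cells, against 7 in cluster 1 and 8 in cluster 3, and Hba-a1 had a median of 59968 RPKM. Cluster 1 held 12 cells (20.7%) and had a median Hba-a1 of 227647 RPKM. No cluster was given a cell type. Early progenitor (BFU-E) markers were low in all clusters, with mean scores of 0.70, 0.64 and 0.024 on the log2 scale in clusters 1, 2 and 3, and 0.046 in cluster 1 without its 3 marker-poor cells. The genes that defined cluster 3 against all other kept cells were globin genes, led by Hbq1b at 4.86 and Hbb-y at 4.52. Cluster 2 was defined by Cdk4 (7.32), Mif (7.01), Pebp1, Nop10 and Nhp2, and cluster 1 by Lsm7 (4.46), Snrpd2 (4.39), Gapdh and Rps18. The number of genes detected was 2932.5, 3870 and 1519 at the median in clusters 1, 2 and 3, while estimated depth in units of 1000 reads was 6922, 6525 and 7896. The mean silhouette was 0.352 with 3 clusters and 0.422 with 2 clusters, and the first component held 31.7% of the variance. Clusters were ordered by the mean erythroblast score, 4.27, 4.79 and 5.19, so that clusters 1 and 3 were the ends compared. Without its marker-poor cells cluster 1 scored 5.52, above cluster 3. Its late progenitor score was then 5.82. That of cluster 2 was 5.83 with its 1 marker-poor cell still included, so these 2 scores are not on like terms. In 8 other settings the end with the lower score was the one richer in alpha-globin.

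**Figure D1:**
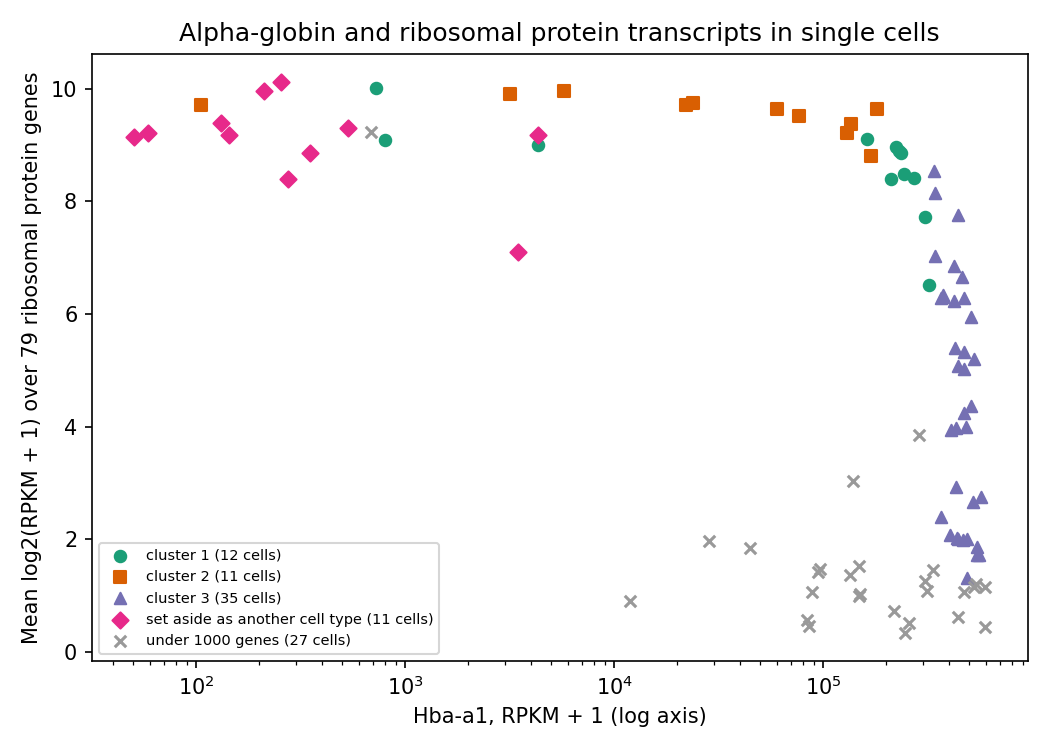
Each point is a single cell; the x axis is Hba-a1 in RPKM + 1 on a log axis and the y axis is the mean log2(RPKM + 1) over 79 ribosomal protein genes. Cluster 3 cells, with Hba-a1 medians of 443162 RPKM, span ribosomal protein means of 1.31 to 8.53, while cluster 2 cells lie between 8.80 and 9.96.

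Transcripts of all 79 cytoplasmic ribosomal protein genes were lower in cluster 3 than in cluster 1 by at least 1 on the log2 scale. The median difference was -4.25, and the mean over the genes was 8.63 ± 0.86 in cluster 1 (SD, 12 cells), 9.57 ± 0.33 in cluster 2 (11 cells) and 4.47 ± 2.13 in cluster 3 (35 cells). Rps18 (-5.87), Rpl10 (-5.42) and Rpl32 (-5.34) were among the genes with the largest differences. Against cluster 2 the median difference was -5.21, again with 79 of 79 genes lower. Random lists matched on expression had a median of -1.52, and the ribosomal protein median lay at percentile 0 of 10000 such lists. In the ribosome biogenesis list, 6 of 22 genes were lower and 0 higher, with a median of -0.93 (percentile 0.12, random median -0.45). The largest of these differences were in the nucleolar genes Nhp2 (-3.82), Npm1 (-3.42), Ncl (-2.99) and Nop56 (-2.64), and Npm1 differed by -6.88 between clusters 3 and 2. The biogenesis median was -0.80, with 7 genes lower, when the marker-poor cells were left out. Over 2118 genes kept out of the clustering and of all lists, the median difference was -1.19 as deposited, and it shifted by -0.12 after rescaling every cell to a total of 1000000 and by 0.36 after removing globin genes and rescaling. Relative to that median, ribosomal protein genes differed by -3.06, -3.42 and -2.63 under these scalings. Within run codes SCP-1706013, SCP-170608 and SCP-1706080, median ribosomal protein levels were 8.40, 9.01 and 8.66 in cluster 1 and 3.44, 5.71 and 5.20 in cluster 3. In cells with at least 2000 genes the median shrank to -1.77 with clusters rebuilt (random median -0.98). It shrank to -1.29 with clusters held (random median -0.95), where 5 cells of cluster 3 were left. There 59 of 79 genes were lower by at least 1, by size alone without the condition on run codes. Without the marker-poor cells the ribosomal protein median was -3.98, and with clusters ordered by score its sign turned in 7 of 22 settings fixed beforehand.

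**Figure D2:**
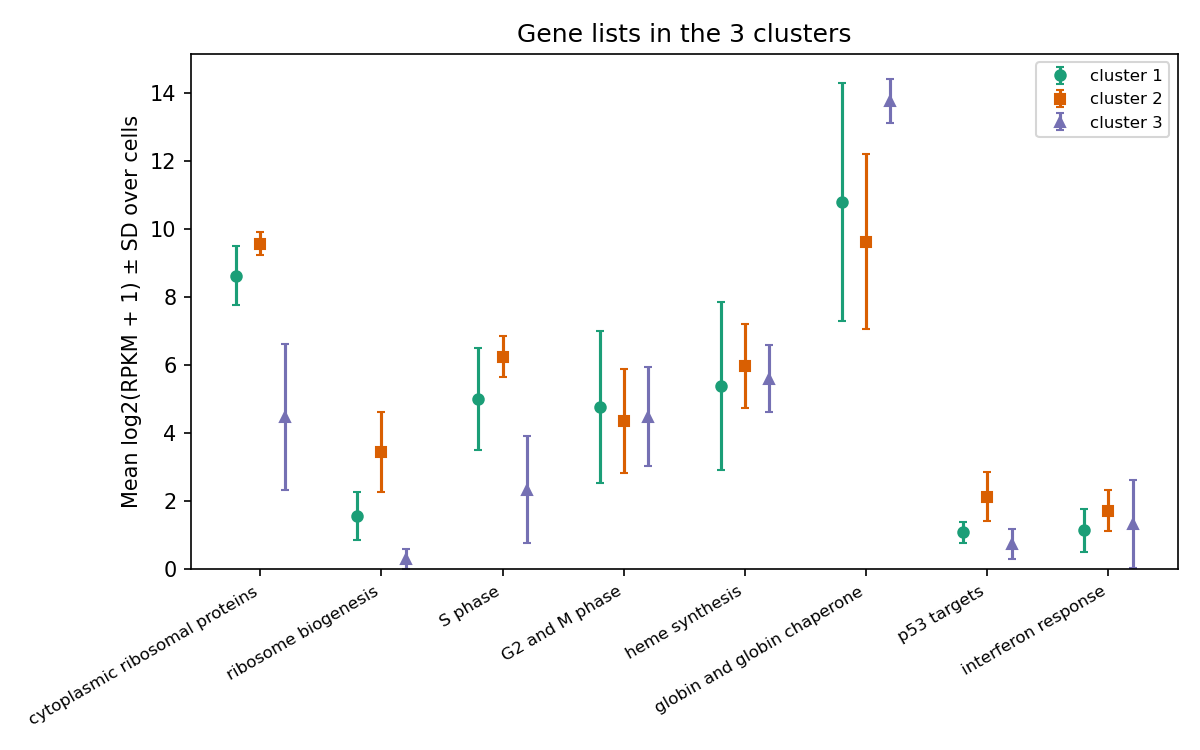
Mean log2(RPKM + 1) over the genes of 8 lists, on the y axis, in clusters 1, 2 and 3; points are means over 12, 11 and 35 cells and bars are SDs over cells. Ribosomal proteins are at 8.63, 9.57 and 4.47 and S phase genes at 5.00, 6.25 and 2.34, while the globin list is at 10.8, 9.62 and 13.76.

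Globin transcripts were higher in cluster 3 than in cluster 1 for 9 of 10 measured genes, which include 3 pairs of near-identical copies, with a median difference of 3.05, at percentile 100 of the random lists. The adult beta-globin genes Hbb-b1 (3.42), Hbb-bs (3.42) and Hbb-b2 (3.34) and the embryonic gene Hbb-bh1 (3.45) had the largest differences, and the higher genes also included Eif2ak1, a heme-regulated kinase (1.80). Hba-a1 took 31.0% of estimated reads in cluster 3, 15.9% in cluster 1 and 4.19% in cluster 2 at the median. Near-identical copies had nearly the same values, with gaps of at most 0.011 on the log2 scale between Hba-a1 and Hba-a2 and 0.039 between Hbb-b1 and Hbb-bs, so they were not told apart. Against cluster 2 the globin median was 4.12, and without the marker-poor cells it was 1.05 against cluster 1, with 4 of 10 genes higher and Hbb-b2 at 0.99. With clusters ordered by score the globin median was below 0 in 6 of 22 settings fixed beforehand, with a lowest value of -2.66. Heme synthesis genes were near level, with a median of 0.18 and 1 gene higher and 1 lower of 14, while random lists had a median of -1.25 (percentile 99.97). Alas2, the enzyme of the committed step of heme synthesis in red cells, was higher by 2.65, and Tmem14c, a mitochondrial porphyrin transporter, differed by -3.19. Urod (1.65) and Fech (1.34) did not keep 1 direction in all run codes. When the marker-poor cells were left out the heme synthesis median was -0.84, with 5 genes lower and 0 higher, and Alas2 was at 0.51, Urod at -0.53 and Fech at -0.79. Rescaling to a total of 1000000 also turned the heme synthesis median to -0.10, and relative to all held-out genes it was 1.37, 1.21 and 1.505 as deposited, rescaled, and without globin. In cells with at least 2000 genes the heme synthesis median was 0.81 with clusters rebuilt, with 4 genes higher by at least 1 and 0 lower. With clusters held it was 1.33, with 8 higher and 0 lower and 5 cells of cluster 3 left. Counts at 2000 genes go by size alone, without the condition on run codes, unlike the 1 higher and 1 lower above. The marker-poor cells were kept in them. In the heme export and breakdown list 4 of 7 measured genes were lower and 0 higher, with a median of -1.003 (percentile 46.9). Blvra, a biliverdin reductase, differed by -2.80, Pgrmc1 by -1.71, Hmox2 by -1.47 and Slc48a1 by -1.003, whereas Blvrb (1.42) and Abcg2 (-0.33) had no common direction over run codes. In this list the marker-poor cells changed several values, with a median of -1.48 and 5 genes lower without them, Blvrb at -1.41, Abcg2 at -1.48 and Slc48a1 at -0.38. The heme exporter genes Flvcr1 and Flvcr2 and the globin chaperone gene Ahsp were not analysed here. Iron handling genes had a median of -0.29 (percentile 89.9), with 1 of 14 lower, Pcbp1 (-2.13). The ferritin genes Fth1 (-0.85) and Ftl1 (-0.66) differed by less than 1, but Fth1 was at -1.22 and 4 of 14 genes were lower without the marker-poor cells (median -0.45). Slc25a37, the mitochondrial iron importer, was higher by 3.03 than in cluster 2 and by 1.39 than in cluster 1, with no common direction over run codes in the latter and -0.19 without the marker-poor cells.

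Genes of S phase were lower in cluster 3, in 19 of 22 members, with a median difference of -2.64 (percentile 2.03, random median -1.73), and against cluster 2 the median was -3.79 (percentile 4.98, random median -2.99). The replication genes Mcm4 (-4.43), Gins2 (-4.24), Mcm6 (-4.04) and Cdc45 (-3.78) had the largest differences, and the list mean was 5.00 ± 1.49 in cluster 1, 6.25 ± 0.60 in cluster 2 and 2.34 ± 1.57 in cluster 3. Genes of G2 and M phase had a median of -0.14, 1 of 20 higher and 3 lower, at percentile 99.99 of lists with a random median of -1.91. Ube2c, which takes part in degrading mitotic cyclins, was higher by 2.57, while Cdc20 (-3.56), Aurkb (-2.20) and Plk1 (-1.07) were lower and Aurka (-1.17) had no common direction over run codes. Against cluster 2 the G2 and M median was 0.32, and without globin genes it was 0.63 against cluster 1, so its sign depended on the scaling. It was -0.81, with 1 gene higher and 7 lower, without the marker-poor cells. Of 10 cyclin-dependent kinase inhibitors and G1 cyclins or kinases, 1 was higher and 2 lower (median -0.56, percentile 75.2). Cdkn2d, an inhibitor of CDK4 and CDK6, was higher by 2.07, and Ccnd3 (-3.95) and Cdk4 (-3.89) were lower. Between clusters 3 and 2, Cdkn2d differed by 4.16 and Cdk4 by -8.31. Leaving out the marker-poor cells gave medians of -3.49 for S phase, with 19 genes lower, and 0.0010 for the kinase inhibitors and cyclins. With clusters ordered by score, the S phase median was below 0 in 14 of 22 settings fixed beforehand and reached 5.71, and it was above 0 even where the end with the higher score was richer in alpha-globin, at 0.87 with no gene minimum and 1.05 with no cell set aside.

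Erythroid transcription factor genes had a median difference of -0.59 (percentile 89.2), with 4 of 21 lower and 0 higher. Bcl11a (-2.91), Ldb1 (-1.63), Gfi1b (-1.17) and Gata1 (-1.15) were lower, and Tal1 differed by 0.90. When the marker-poor cells were left out, 6 factor genes were lower (median -0.50) and Gata1 differed by -2.90. Gata1 differed by -2.77 between clusters 3 and 2, and Kit was at 1 RPKM or more in 0 of 58 kept cells. In the p53 list, named since defects of ribosomal proteins are known to activate p53, the median difference was -0.020, with 2 of 20 genes lower and 0 higher (percentile 97.3). Only 3 of the 20 were detected in at least 50% of the cells of an end cluster, with a median of -2.21. The list median and percentile thus rest mostly on genes seen in few cells. The lower genes were Rps27l (-3.58) and Trp53 (-2.21), and Btg2 (1.18) had no common direction over run codes and was at 0.19 without the marker-poor cells, where 1 gene of the list was higher. Cluster 2 had the highest levels of Trp53 (mean log2 6.82), Bax (6.16), Mdm2 (3.51), Ccng1 (3.18), Cdkn1a (2.83) and Phlda3 (2.54), and 6 of 20 genes were lower in cluster 3 than there, with a median of -0.26. Most matched random lists differed more (random median -0.60, percentile 96.0), and 1529 of 2118 held-out genes were also lower by at least 1 in cluster 3 than in cluster 2. Survival and apoptosis genes had a median of -0.56 (percentile 66.9), with Casp8 (-1.62) and Bid (-1.37) lower of 15. Mcl1 (-1.02) and Bnip3l (-0.12), the members detected in at least 50% of the cells of an end cluster, had no common direction over run codes, and 0 genes were lower and 1 higher without the marker-poor cells (median -0.34). No gene of the 12 of the EPO and STAT5 list reached a difference of 1, and the median was 0 (percentile 94.3), with no member detected in at least 50% of the cells of an end cluster.

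Among stress genes, the heat shock genes Hspa8 (-5.04), Hsp90aa1 (-2.70) and Dnajb1 (-2.36) and the immediate early gene Ier2 (-1.68) were lower in cluster 3. They belong to the immediate early and heat shock list, in which 4 of 12 were lower and 0 higher, with a median of -1.70 (percentile 0) that was -0.35, with 3 lower, without the marker-poor cells. In the integrated stress response list 1 of 16 was higher and 4 lower (median -0.49, percentile 21.5), with Ppp1r15a at 1.32, Atf4 at -1.62, Shmt2 at -1.33, Mthfd2 at -1.30 and Ddit3 at -1.18, while Asns (-1.34) had no common direction over run codes. In the oxidative stress list 1 of 12 was higher and 3 lower (median -0.54, percentile 92.3), with Nqo1 (1.35) higher and Prdx1 (-4.77), Sod1 (-4.09) and Gclc (-1.46) lower, while Gclm (1.28) had no common direction over run codes. Without the marker-poor cells 0 genes were higher in the integrated stress, oxidative stress and interferon lists, with 5, 4 and 1 lower, and Ppp1r15a was at 0.71 and Gclm at -0.43. The interferon list had a median of 0.16 (percentile 99.97), with 1 of 8 higher, Irf7 at 1.73, and 1 lower, Ifitm3 at -3.17. Only 1 of the 8 was detected in at least 50% of the cells of an end cluster. In cells with at least 2000 genes the interferon median was 0.48 with clusters rebuilt, with 2 genes higher by at least 1 and 0 lower. With clusters held it was 1.11, with 5 higher and 0 lower and 5 cells of cluster 3 left. Both of these counts go by size alone, without the condition on run codes, and the marker-poor cells were kept. Of the 5 sex-linked genes, Xist was detected in 42 of 58 kept cells and Ddx3y in 0, and the list median was 0 (percentile 50), with Xist at -1.58 as the only lower gene.

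Beyond the lists, 933 of the 2118 held-out genes were lower by at least 1 in cluster 3 than in cluster 1 and 19 were higher. The largest differences downward were in the splicing factor genes Lsm7 (-6.05) and Snrpd2 (-5.89), the cyclophilin gene Ppia (-5.86), the mitochondrial genes Mrpl33 (-5.64) and Sdhd (-5.52), and in 1110004F10Rik (-5.50), Eef1a1 (-5.39), Gstp1 (-5.32), Cers2 (-5.29) and Gm12191 (-5.27). The largest upward differences were in Hbq1a, a theta-globin gene (3.45), Rsad2, an interferon-induced gene (2.99), Fn3k (2.44), Gch1 (2.38), Ube2l6 (2.14), Smox (1.91), Ptp4a3 (1.70), Gmppb (1.55), Gm867 (1.53) and Tfdp2 (1.43). Hbq1b, a related gene, was among the clustering genes, so the Hbq1a difference was not independent of how the clusters were built. Between clusters 3 and 2, 1529 genes were lower and 27 higher, with a median of -2.33. Between clusters 1 and 2, 750 were lower and 30 higher, with a median of -0.97. Leaving out the marker-poor cells, 932 genes were lower and 14 higher in cluster 3 than in cluster 1, and Ube2l6 (0.22), Gm867 (0.60) and Tfdp2 (0.68) were under a difference of 1. By size alone, without the condition on run codes, 1200 were lower and 28 higher. With clusters rebuilt and ordered by score, the direction turned in some settings fixed beforehand. Without run SCP-1706013, 560 were higher and 26 lower, and without run SCP-1706080, 1127 were higher and 45 lower. With clusters held, leaving out a run code gave 31 to 49 higher. In simulated data 7.53% of unchanged genes passed the rule of size with its condition on run codes, and the rule is not a test. The 19 higher genes make up a smaller share of the 2118 than that. However, the simulated share counts both directions and no shift over all genes, while the held-out genes had a median difference of -1.19. It thus neither sets the 19 apart from such calls nor counts against them.

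Run codes were read from the sample descriptions, and they conflict with the sample titles, which give the code SCP-1706080 to all 96 cells, so that the codes differ for 44 cells. Which of these is right was not settled. The descriptions gave the 96 cells 81 different well positions, so some positions recur. If the titles' 1 code stood for 1 plate, it would not account for this. The 3 codes of the descriptions, SCP-1706080 (52 cells), SCP-170608 (25 cells) and SCP-1706013 (19 cells), each held cells of all 3 clusters. Median log2 Rpl11 was 5.94, 7.68 and 6.48 in the kept cells of these codes. Within cluster 3, median Rpl11 was 0.528, 2.57 and 2.77 RPKM, and within cluster 1 it was 221, 348 and 340 RPKM, so Rpl11 was lower in cluster 3 in each code. Cluster 3 made up 19 of 27 kept cells (70.4%), 8 of 17 (47.1%) and 8 of 14 (57.1%), with overlapping exact intervals. Hba-a1 in cluster 3 was at a median of 469528, 439556 and 448093 RPKM. By well columns of the capture plate, cluster 3 made up 16 of 29 kept cells (55.2%) in columns 1 to 3 and 7 to 9 and 19 of 29 (65.5%) in the others.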

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

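The tests of captures of 2 cells, of carried-over RNA, of run codes, of dilution by globin, of short transcripts, of read depth, of a minimum of 2000 genes with clusters held and of cells with few erythroid markers were chosen only after the result was seen.

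Cells outside the comparisons listed genes of other lineages, which is no test, since they were set aside for markers of those lists. Mpo had a median of 11446 RPKM in the 7 cells that met the neutrophil list (7333 to 18579). Elane, the gene of neutrophil elastase, had a median of 10507 RPKM in these cells (869 to 24064). Ly86 had a median of 399 RPKM in the 2 cells that met the monocyte list alone. Prss34 was at 45416 RPKM in the cell that met the basophil list, and Nkg7 at 8032 RPKM in the cell that met the T or NK cell list. Among the cells under 1000 genes, Hba-a1 had a median of 538799 RPKM in the 5 cells with over 1000000 estimated reads, against a floor of 0.766 RPKM that 3 reads would give. In the 18 such cells with fewer reads its median was 136155 RPKM, against a floor of up to 146 RPKM.

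For the cells with myeloid, basophil or NK genes, 3 technical explanations were tested. RNA carried over between chambers stays open. Median Mpo in the 54 kept cells with erythroid markers was 0 percent of that in the 7 cells, with 36 at 0 and a highest value of 1.62 RPKM. However, cells with many neutrophil markers had been taken out of the kept cells, and Mpo does not bear on the basophil and NK genes. Among 27 cells under 1000 genes, 4 listed Mpo at 236 to 2657 RPKM, and kept marker-poor cells 3 and 68 listed it at 371 and 28.0 RPKM. Captures with a partner like the kept erythroid cells are argued against by the count of erythroblast markers, a criterion added later. The 11 cells had at most 2 such markers (3 at 5 RPKM) against 7 to 16 in the kept ones, and 9 listed Hba-a1 at 532 RPKM or less. The first criterion was undecided, since 18.2% of the 11 cells had at least 3 late progenitor markers, between its bounds. An early progenitor as partner stays open. A single run as the source stays open, since descriptions give these cells 3 codes but titles give all cells 1, and no biological explanation was tested, since the design names 1 group.

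Lower ribosomal protein transcripts in the globin-rich cluster were weighed against 5 technical explanations. Dilution by globin reads in 1 proportion over all other genes is argued against. After removing globin genes and rescaling, the median difference was still -3.47. However, rescaling leaves values of 0 at 0, so lost detection through globin reads stays open. A loss of all transcripts alike and a loss of short transcripts were not decided. The list lay at percentile 0 of random lists matched on expression (lowest of these -2.87). It also lay at percentile 0 of lists matched on expression and length (lowest -2.94), so it fell further than the matched genes. However, the match used the mean over clusters 1 and 3, which contains the difference itself. Matched genes need not have had the same level in cluster 1, and random lists lacked the co-expression of real lists. Total depth, globin reads included, was 1.14 times that of cluster 1, which argues against fewer reads in total. Reads left for other genes were not compared. The difference was -3.98 without the cells of few erythroid markers, which argues against the presence of those cells as the cause. Whether those cells were non-erythroid was not settled. In cells of at least 2000 genes the difference was -1.77 with clusters rebuilt (percentile 0, random median -0.98). With clusters held it was -1.29 (percentile 0.06, random median -0.95, 5 cells of cluster 3), with the marker-poor cells of cluster 1 kept. Much of the difference left was thus shared by matched genes. A loss of RNA in cells with few genes stays open for much of the size of the main difference. No biological explanation was tested, since the design names 1 group.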

How the results depend on the processing

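Tests with ends chosen by alpha-globin, with clusters held, with cluster 2 as the low end, with the mean of transcript values, without the condition on run codes, with a minimum of 2000 genes and clusters held, and without the 4 cells of few erythroid markers were chosen only after the results were seen. The direction of a comparison between end clusters depended on which clusters the erythroblast score placed at the ends. In 8 settings the low end was richer in alpha-globin than the high end, and ribosomal protein, S phase and globin differences then all changed sign. Without a gene minimum per cell, ribosomal protein and S phase differences changed sign with globin still higher, and with no cell set aside S phase was at 1.05 with globin at 9.09. The sign changed in 56 to 72 of the 77 named genes in those 8 settings, in 0 to 48 in the 15 other settings fixed before the data were examined, in 0 to 5 in 7 settings with clusters held and in 0 to 9 with ends chosen by alpha-globin, which makes 796 of 4081 gene values. Single genes have no test and are given here as these counts. With ends chosen by alpha-globin, the ribosomal protein median was below 0 in 23 of 23 settings, from -7.17 to -1.77, and S phase in 23 of 23, from -5.71 to -2.13, while the sign of the globin list was fixed by that choice of ends. These settings re-use the same cells, and both lists had already been seen to be lower in the globin-rich cluster. The 23 settings are thus no independent support. By the rule fixed beforehand the ribosomal protein median was below 0 in 15 of 22 settings, from -5.65 to 7.17, and with clusters held and a minimum of 1000 genes it lay from -5.21 to -3.47. Apart from the choice of ends, the cause was not tested. At a minimum of 2000 genes per cell the ribosomal protein median shrank to -1.77 with clusters rebuilt and to -1.29 with clusters held, where 5 cells of cluster 3 were left. A list or level counts as changed when it moved by more than 1 SD over cells or, for a list differing by at least 1, changed sign, a share when it left its exact interval, and a number of genes or cells when it differed by over 1.5 times. No paired analysis was possible because all cells carry 1 group label and are compared without a test. Depth limits low levels, and in the 18 cells with at most 1000000 estimated reads and under 1000 genes most genes were below detection.

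These values changed under settings fixed before the data were examined; medians are of list differences on the log2 scale, and the top cluster is that with the highest erythroblast score. With pseudocount 0.1, 31 held-out genes were higher. With pseudocount 10, the top cluster held 6.90% of cells, with a median of -0.31 for heat shock. With rescaling to a total of 1000000, the top cluster held 20.7% of cells and 103 held-out genes were higher, with medians of -2.38 for ribosome biogenesis, 0.36 for heme export, -0.45 for S phase and -0.41 for EPO response. With division by each cell's median, the top cluster held 3.45% of cells and 73 held-out genes were higher, with a median of -2.34 for ribosome biogenesis. With no gene minimum per cell, median Rpl11 was 1.92, Rpl11 was detected in 52.9% of cells, run medians spanned 6.59 and 758 held-out genes were higher and 10 lower, with medians of 2.52 for ribosomal proteins, 4.26 for heme synthesis, 1.36 for heme export, 0.62 for iron handling, 0.21 for erythroid factors, 0.87 for S phase, 2.43 for G2 and M, 0.37 for cyclin inhibitors, 0.28 for apoptosis, 0.32 for stress response, 0 for heat shock and 2.05 for oxidative defence. With a minimum of 2000 genes, Rpl11 was detected in 96.4% of cells, the top cluster held 35.7% of cells and 46 held-out genes were higher, with medians of -2.42 for ribosome biogenesis and -0.43 for heat shock. With no cell set aside, the top cluster held 29.0% of cells and 378 held-out genes were higher, with medians of -0.60 for ribosomal proteins, 5.46 for heme synthesis, 0.68 for iron handling, 9.09 for globin, 1.05 for S phase, 2.69 for G2 and M and 0.58 for oxidative defence. With no filter on low genes, the top cluster held 17.2% of cells and 1233 held-out genes were higher and 99 lower, with medians of 0.89 for ribosomal proteins, 2.06 for ribosome biogenesis, 0.93 for heme export, 0.46 for iron handling, -0.079 for globin, 0.38 for erythroid factors, 1.59 for S phase, -0.060 for heat shock and 0.93 for oxidative defence. With clusters from the held-out genes, the top cluster held 32.8% of cells and 713 held-out genes were higher and 8 lower, with medians of 4.03 for ribosomal proteins, 1.34 for heme export, -0.54 for globin, 0.51 for erythroid factors, 2.71 for S phase, 0.16 for heat shock and 0.61 for oxidative defence. With 2 clusters, 1447 held-out genes were lower. With 4 clusters, the top cluster held 29.3% of cells. With 5 clusters, the top cluster held 15.5% of cells and 63 held-out genes were higher, with medians of -1.13 for ribosomal proteins, -0.49 for EPO response and -0.30 for heat shock. With 6 clusters, the top cluster held 8.62% of cells and 98 held-out genes were higher and 1404 lower, with a median of -2.77 for ribosome biogenesis. With k-means, the top cluster held 31.0% of cells, with medians of -2.31 for ribosome biogenesis and -0.24 for heat shock. With 5 principal components, the top cluster held 25.9% of cells and 849 held-out genes were higher and 11 lower, with medians of 4.28 for ribosomal proteins, 0.51 for ribosome biogenesis, 1.63 for heme export, 0.49 for iron handling, -0.76 for globin, 0.45 for erythroid factors, 3.29 for S phase, 0.24 for apoptosis, 0.21 for heat shock and 0.50 for oxidative defence. With 500 most variable genes, the top cluster held 22.4% of cells and 709 held-out genes were higher and 13 lower, with medians of 3.92 for ribosomal proteins, 1.53 for heme export, 0.52 for iron handling, -0.61 for globin, 0.36 for erythroid factors, 2.83 for S phase, 0.28 for apoptosis, 0.22 for heat shock and 0.50 for oxidative defence. Without run SCP-1706013, the top cluster held 4.55% of cells and 560 held-out genes were higher and 26 lower, with medians of 3.31 for ribosomal proteins, 0.61 for heme export, -0.40 for globin, 0.45 for erythroid factors, 2.48 for S phase, 0 for heat shock and 0.73 for oxidative defence. Without run SCP-170608, 6 cells were set aside and 39 held-out genes were higher, with medians of -2.54 for ribosome biogenesis, -1.12 for iron handling and -1.39 for stress response. Without run SCP-1706080, 6 cells were set aside, the top cluster held 6.45% of cells and 1127 held-out genes were higher and 45 lower, with medians of 7.17 for ribosomal proteins, 2.10 for ribosome biogenesis, 3.31 for heme export, 0.53 for iron handling, -2.66 for globin, 0.98 for erythroid factors, 5.71 for S phase, 0.46 for apoptosis, 0.24 for heat shock and 1.20 for oxidative defence. With only members detected in at least 50% of the cells of an end cluster, the list differences had medians of -2.82 for ribosome biogenesis, -2.21 for p53 targets, -3.89 for cyclin inhibitors, -1.24 for stress response, -3.17 for interferon response and -1.58 for sex-linked.

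Other rebuilds were added later. With the mean of transcript values, the top cluster held 31.6% of cells and 631 held-out genes were higher and 20 lower, with medians of 3.05 for ribosomal proteins, 0.72 for heme export, -0.33 for globin, 0.35 for erythroid factors, 2.61 for S phase, 0.050 for heat shock and 0.64 for oxidative defence. With rebuilt clusters without the 4 cells of few erythroid markers, the top cluster held 24.1% of cells and 792 held-out genes were higher and 8 lower, with medians of 4.16 for ribosomal proteins, 0.59 for ribosome biogenesis, 1.37 for heme export, 0.46 for iron handling, -0.76 for globin, 0.42 for erythroid factors, 2.89 for S phase, 0.29 for apoptosis, 0.24 for heat shock and 0.44 for oxidative defence. With clusters 1 and 3 held as built, other changes were these. With removal of globin with rescaling, 46 held-out genes were higher. With rescaling to a total of 1000000, 6 held-out genes were higher. With removal of the 4 cells of few erythroid markers, the list differences had a median of -0.35 for heat shock. Without run SCP-1706013, 49 held-out genes were higher. Without run SCP-170608, 31 held-out genes were higher. Without run SCP-1706080, 38 held-out genes were higher. With cluster 2 in place of cluster 1, 1529 held-out genes were lower, with medians of -3.22 for ribosome biogenesis and -0.50 for EPO response.

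With ends chosen by alpha-globin, changes by setting were these. With pseudocount 0.1, 37 held-out genes were higher and 1626 lower, with medians of -4.12 for ribosome biogenesis, -1.35 for iron handling, -1.55 for erythroid factors, -5.64 for S phase, -0.77 for EPO response and -1.35 for stress response. With pseudocount 10, 12 held-out genes were higher, with a median of -0.31 for heat shock. With rescaling to a total of 1000000, 33 held-out genes were higher and 1729 lower, with medians of -4.30 for ribosome biogenesis, -3.80 for heme export, -1.55 for iron handling, -1.87 for erythroid factors, -2.12 for cyclin inhibitors, -1.44 for apoptosis, -0.76 for EPO response, -1.41 for stress response and -2.18 for oxidative defence. With division by each cell's median, 73 held-out genes were higher, with a median of -2.34 for ribosome biogenesis. With no gene minimum per cell, 1477 held-out genes were lower. With a minimum of 2000 genes, 46 held-out genes were higher, with medians of -2.42 for ribosome biogenesis and -0.43 for heat shock. With no cell set aside, 125 held-out genes were higher and 1872 lower, with medians of -3.62 for ribosome biogenesis, 3.52 for heme synthesis, 10.96 for globin, 2.20 for G2 and M, -1.65 for cyclin inhibitors and -2.12 for apoptosis. With no filter on low genes, 1847 held-out genes were lower, with medians of -3.35 for ribosome biogenesis, -0.98 for iron handling, -0.55 for EPO response, -0.39 for heat shock and -1.49 for oxidative defence. With clusters from the held-out genes, 1501 held-out genes were lower, with medians of -2.77 for ribosome biogenesis, -4.86 for S phase, -0.38 for EPO response and -0.40 for heat shock. With 2 clusters, 1447 held-out genes were lower. With 4 clusters, 5 clusters and 6 clusters, 34 held-out genes were higher and 1598 lower, with medians of -3.17 for ribosome biogenesis, -5.38 for S phase and -0.49 for EPO response. With k-means, 1508 held-out genes were lower, with medians of -2.46 for ribosome biogenesis and -4.83 for S phase. With 5 principal components, 33 held-out genes were higher and 1519 lower, with medians of -3.37 for ribosome biogenesis, -1.002 for iron handling, -0.53 for EPO response and -0.48 for heat shock. With 20 principal components, 1509 held-out genes were lower, with medians of -2.85 for ribosome biogenesis and -0.39 for EPO response. With 500 most variable genes, 1509 held-out genes were lower, with medians of -2.57 for ribosome biogenesis, -0.38 for EPO response and -0.37 for heat shock. With 2000 most variable genes, 34 held-out genes were higher and 1513 lower, with medians of -3.22 for ribosome biogenesis and -0.49 for EPO response. Without run SCP-1706013, the list differences had medians of -5.14 for S phase, -0.68 for heat shock and -1.49 for oxidative defence. Without run SCP-170608, 39 held-out genes were higher, with medians of -2.54 for ribosome biogenesis, -1.12 for iron handling and -1.39 for stress response. Without run SCP-1706080, 45 held-out genes were higher, with medians of -7.17 for ribosomal proteins, -3.31 for heme export, -5.71 for S phase and -0.24 for heat shock. With the mean of transcript values, 29 held-out genes were higher and 1555 lower, with medians of -2.31 for ribosome biogenesis, -5.24 for S phase, -0.34 for heat shock and -1.56 for oxidative defence. With rebuilt clusters without the 4 cells of few erythroid markers, 32 held-out genes were higher and 1409 lower, with medians of -3.06 for ribosome biogenesis, -0.48 for EPO response and -0.43 for heat shock.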

Other observations

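The tests on embryonic globin were chosen before their results were seen, while the interferon cells, the deep cells with few genes and the spread of ribosomal protein levels were looked at only after the result was seen.

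Interferon-induced genes stood out in a few cells of cluster 3. Cells 21 and 32, both of run code SCP-1706080, had interferon list means of 5.19 and 4.97 on the log2 scale, and the next highest kept cells had 2.84 and 2.74. They listed Isg15, a ubiquitin-like modifier, at 128 and 719 RPKM, Irf7 at 210 and 406 RPKM, Ifitm3 at 3795 and 948 RPKM and Usp18 at 67.1 and 179 RPKM. Ifit1 and Ifit3, also on the list, were listed at 0 in both cells. Rsad2 was detected in 23 of 35 cells of cluster 3, in 3 of 12 of cluster 1 and in 3 of 11 of cluster 2.

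Ribosomal protein levels spanned a wide range within cluster 3, from 1.31 to 8.53 on the log2 scale, with 13 of 35 cells under 3 and 11 at 6 or more. The 5 cells under 1000 genes with over 1000000 estimated reads lay below this range. They had a median ribosomal protein level of 1.15 and 37.7% of estimated reads from Hba-a1. These cells were picked for having few genes, and a loss of RNA in them was not tested. Of the cells under 1000 genes, cells 13, 81 and 82 listed Mpo at 1469 to 2657 RPKM and had too few low values for a depth estimate.

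Embryonic globin genes were listed in adult marrow cells. In the 35 cells of cluster 3, Hbb-bh1 lay at a median of -8.39 relative to Hbb-b1 on the log2 scale, with an SD of 0.60, while Hbb-y lay between -9.56 and -6.12 in 26 cells and at -14.8 or below in 9. Reads shared with adult globin in a fixed proportion would hold the Hbb-y ratio nearly constant. Its SD of 3.12 argues against 1 fixed proportion over all 35 cells. This SD spans the gap between the 26 and the 9 cells, so it does not bear on the 26 cells alone. In these 26, with a median of -8.87, shared reads stay open, as they do for Hbb-bh1. A subset of cells that expresses Hbb-y may exist but was not settled, since the highest ratio was 7.14 times the median, between the bounds set for the test. That highest ratio came from 1 cell, cell 85, with Hbb-y at 4987 RPKM. In the other cluster 3 cells Hbb-y was at 816 RPKM or less. Hba-x lay between -9.20 and -8.11 relative to Hba-a1 in 12 cells and at -11.6 or below in 23. No biological explanation was tested, since the design names 1 group.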
